A study of Mus musculus with 6 samples.

How the data were processed

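Blood monocytes of mice were profiled as single cells on 6 plates of 384 wells, 2304 wells in all: 2 plates of Cx3cr1-cre YFP total monocytes, 3 of wild-type total monocytes and 1 of wild-type monocytes with intermediate Ly6C. The deposited values are raw counts of molecules per gene and well, per the labels' protocols and the values themselves, with 33924 gene rows and 92 spike-in rows; the authors' counting collapsed reads by their molecular identifiers. Per the submitters' processing notes, base calls were made with bcl2fastq 2.15.0.4 and the genome build was mm9; the aligner, the annotation and the counting programme are not given in the sources used here. No coordinates are given, since the annotation of mm9 was not used here. The deposited table of wells gives batch, plate and the number of cells sorted (0 or 1). Index-sort fluorescence was not used here, so a planned assignment of classes by Ly6C fluorescence was not run.

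Spike-in rows were set aside. Wells sorted with a cell numbered 2280, and 24 wells were empty. Cells with at least 400 UMIs were kept. Empty wells held a median of 2.66 to 5.29% of the median of the kept cells of their plate. No doublet caller was run: each well was sorted with a single cell, and the 2% of cells with most UMIs per plate were left out as an alternative. Counts of each cell were scaled to 1000 and log-transformed (natural log of 1 plus the value). Cells were clustered with Leiden at resolution 0.5 on a graph of 30 neighbours, built on 47 genes of 3 fixed marker lists (classical, non-classical, and MHC-II or dendritic cell-like monocytes) that had at least 50 UMIs over kept cells, with scanpy 1.11.5 and leidenalg 0.10.2. A cluster took its name from the list with most members among its 10 leading genes: 9, 8 and 6 for the 3 clusters. In cells of a class, the median depth relative to the plate was 1.29 for classical-like, 0.87 for non-classical-like and 1.49 for MHC-II-like cells.

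Raw UMIs were summed per plate and class, and sums of under 10 cells were left out. edgeR 4.0.16 (R 4.3.3) was used with filterByExpr, TMM and the quasi-likelihood F test. Classes were compared on the 5 plates of total monocytes with the plate as a block, which is the natural pairing because every class came from each plate; labels carry no replicate numbers. Plates were compared with all 6 plates in 3 groups that share 1 estimate of the spread. Standard errors of log2 folds are the fold over the square root of F. CPM are TMM-normalised means over plates, computed here. Adjusted p-values are Benjamini-Hochberg values, called at 0.05. The 47 clustering genes were left out of tests within or between classes. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, and with fry; p-values were adjusted over the lists of a comparison. Of 632 list symbols, 13 were found under an older name and 1 was not found.

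Named genes follow a rule set before the data were examined. The 12 largest rises and 12 largest falls had to have adjusted p under 0.05, an absolute log2 fold of at least 0.5, at least 30 UMIs and no predicted or combined name, and to move the same way in every plate (or, between plates, to have groups that do not overlap). Up to 4 members of each list were named by lowest p among those with adjusted p under 0.05, with no limit on fold or UMIs. Cebpb, Nr4a1, Irf8, Klf2, Klf4, Cx3cr1, Csf1r, Spi1 and Pou2f2 were named in each class comparison whatever their values. Genes with interaction tests, Xist, Cebpb within the classes of the Cx3cr1-cre comparison and the genes of the closing section outside this rule were chosen after their values were seen.

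The fits were tested on simulated counts with 200 changed genes. The comparison of non-classical-like with classical-like cells (2416 genes) recovered 75% of 2-fold and 92% of 4-fold changes, that of MHC-II-like with classical-like cells (2485 genes) 53% and 92%, that with non-classical-like cells (2485 genes) 61% and 91%, the Ly6C-int comparison (5818 genes) 12% and 53%, and the Cx3cr1-cre comparison (5851 genes) 29% and 72%. False calls were between 1.94% and 8.43% of calls. The counts were drawn around a common mean per gene, without plate effects and with the groups given. For the class comparisons this leaves out that classes were clustered from the same cells, so it does not measure their error. Depth limits precision: the wild-type and Ly6C-int plates had fewer UMIs per cell than the Cx3cr1-cre plates, with medians of 693 to 804 against 1888 and 2029. No pair of plates of one group agreed within sampling noise (chi-square per gene of 2.07 to 3.07), so none was counted as 1. Plates hold different cells, so this shows only that no plate is a copy of another, not that plates came from separate animals.

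Alternatives were DESeq2 1.42.0 size factors and test, no filter on low counts, minima of 200 and 800 UMIs, cells thinned to 400 UMIs, 1000 variable genes in place of markers, Leiden resolution 1.0, equal cell numbers, no replicate block, wild-type plates alone, each plate left out in turn and, chosen after seeing the data, a mixture model for classes and the removal of wells with at least 50 haemoglobin UMIs. Share intervals are exact Clopper-Pearson intervals at 95%. Shares were compared with exact permutation tests over plates.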

Results

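Single blood monocytes of C57BL/6 mice were profiled by MARS-seq, a method in which single cells are sorted by flow cytometry into 384-well plates and the 3′ ends of their transcripts are counted with unique molecular identifiers (UMIs), so that each count stands for one captured molecule. Monocytes had been pre-enriched for CD115, the receptor for the growth factor CSF1, and were sorted as lineage-negative CD11b+ CD115+ cells. Of the 6 plates, 2 held total monocytes of 16-week-old Cx3cr1-cre mice with a YFP reporter in the Rosa26 locus, 3 held total monocytes of 7-week-old wild-type mice, and 1 held wild-type monocytes from a gate of intermediate Ly6C, the surface protein that parts classical (Ly6C-high) from non-classical (Ly6C-low) monocytes. Each plate had 380 wells with a cell and 4 empty wells. The files held 763796 and 745526 UMIs for the Cx3cr1-cre plates, 296532, 256992 and 328888 for the wild-type plates, and 282199 for the Ly6C-int plate. Cells with at least 400 UMIs were kept: 364 and 307 cells on the Cx3cr1-cre plates, 330, 286 and 343 on the wild-type plates and 297 on the Ly6C-int plate, 1927 in all. The kept cells had a median of 1888 and 2029 UMIs on the Cx3cr1-cre plates, 751.5, 693 and 804 on the wild-type plates and 766 on the Ly6C-int plate. Genotype, age, sequencing batch and depth per cell changed together between the Cx3cr1-cre and the wild-type plates. The sex of the animals may have changed too, as set out in the closing sections. The labels do not say which plates came from separate animals, so p-values measure the spread between these plates, which may be technical.

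The title of the series asks how monocytes with little Ly6C depend on the transcription factor C/EBPβ, so the first step was to tell the monocyte classes apart. Clustering on 47 marker genes fixed before the data were examined gave 3 clusters. The first, 403 cells, was led by classical monocyte markers and is called classical-like. The second, 1269 cells, was led by non-classical markers and is called non-classical-like. The third, 255 cells, was led by genes of MHC class II, which presents peptides to CD4 T cells, with the lectin gene Cd209a, and is called MHC-II-like. On the wild-type plates 17.6% ± 2.07 (SD, n = 3) of kept cells were classical-like, 72.5% ± 1.73 were non-classical-like and 9.89% ± 0.558 were MHC-II-like. On the Cx3cr1-cre plates the shares were 31.9% ± 0.0380 (SD, n = 2), 60.1% ± 2.06 and 8.02% ± 2.02. The Ly6C-int plate held 7.07% classical-like cells (exact 95% binomial interval 4.43 to 10.6), 56.9% non-classical-like cells (51.1 to 62.6) and 36.0% MHC-II-like cells (30.6 to 41.8). MHC-II-like cells thus took 3.64 times their wild-type share in the gate of intermediate Ly6C. The classical-like difference from the wild-type plates was -10.6 percentage points, and it was -3.60 with classes from 1000 variable genes and -2.39 in cells thinned to 400 UMIs. The gate itself sets which cells were sorted. An exact two-sided permutation test over plates gave p = 0.25 for each of the 3 shares, the smallest p that 1 plate against 3 can give. For the Cx3cr1-cre plates the exact two-sided p was 0.1 for the classical-like and the non-classical-like share, the smallest that 2 against 3 can give, and 0.2 for the MHC-II-like share. The non-classical-like share was 12.4 percentage points lower on the Cx3cr1-cre plates than on the wild-type plates with the minimum of 400 UMIs. In cells thinned to 400 UMIs the difference was -15.0 points. It was 2.05 points with a minimum of 800, which kept 140, 113 and 175 wild-type and 353 and 299 Cx3cr1-cre cells. Non-classical-like cells then numbered 79, 62 and 109 in place of 240, 202 and 254 on the wild-type plates. On the Cx3cr1-cre plates they numbered 214 and 177 in place of 224 and 180. The share was 5.18 points higher on the Cx3cr1-cre plates at Leiden resolution 1.0. At that resolution 303 cells fell in a cluster without a name, led by genes that include S1pr5 and Nr4a1. It took 67, 65 and 79 of the kept cells of the wild-type plates, 16 and 11 of the Cx3cr1-cre plates and 65 of the Ly6C-int plate (at least 20.3% of the wild-type plates and at most 4.40% of the Cx3cr1-cre plates), so that reversal leaves out more wild-type than Cx3cr1-cre cells. With a minimum of 800 UMIs the classical-like difference went from 14.3 to 8.74 points and the MHC-II-like difference from -1.87 to -10.8. Depth per cell differed between these plates, as given above. Intervals cover counting error only.

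**Figure D1:**
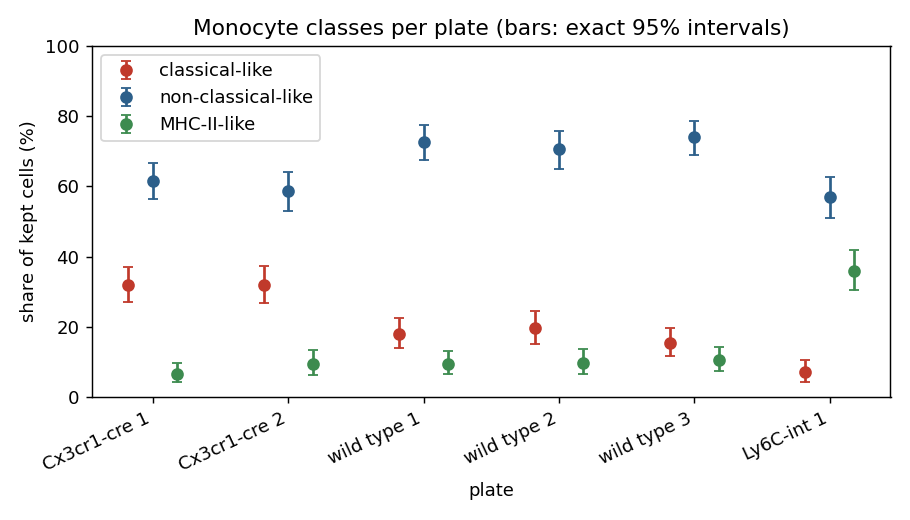
Share of kept cells (%) in each monocyte class on each of the 6 plates; points are shares and bars are exact 95% binomial intervals. The MHC-II-like share was 36.0% on the Ly6C-int plate and 9.89% on average on the wild-type plates.

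Transcripts of other blood cells were rare, with a few exceptions. Over all kept cells the T cell markers summed to 9 UMIs, the NK cell markers to 28, the platelet markers to 50 (47 of them Itgb3), and the basophil and eosinophil markers to 7 each. The B cell list summed to 2103 UMIs, of which 1547 were Ly86, a gene that monocytes also express, and 404 were Ighm. The plasmacytoid dendritic cell list summed to 1136 UMIs, of which 656 were Lair1, and the conventional dendritic cell list to 381. Neutrophil markers made 1824 and 2827 CPM (here without TMM scaling) on wild-type plate 1 and on the Ly6C-int plate, against 451 to 581 on the others. Erythroid markers made 5222 CPM on Cx3cr1-cre plate 1 and at most 108 on any other plate.

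Non-classical-like cells were compared with classical-like cells to see which genes part the classes besides the markers. Cebpb, which encodes C/EBPβ, stood at 1517 CPM in non-classical-like and 748 CPM in classical-like cells, a log2 fold of 1.03 ± 0.11 (SE, adjusted p = 6.3e-11), and was higher in 5 of 5 plates. Cebpa and Cebpd, which encode other C/EBP proteins, went the other way, with log2 folds of -1.47 ± 0.36 (adjusted p = 0.0013) and -1.14 ± 0.26 (adjusted p = 0.0005). Non-classical-like cells also carried more Klf4 (1.61 ± 0.19), Nr4a1 (1.38 ± 0.18), Pou2f2 (1.87 ± 0.32) and Klf2 (0.92 ± 0.12), transcription factors of the myeloid lineage, and more of the receptor genes Cx3cr1 (0.73 ± 0.18) and Csf1r (0.41 ± 0.11). Sfpi1, the files' name for Spi1, which encodes PU.1, rose by 0.43 ± 0.12, and Irf8, a factor of monocyte and dendritic cell development, fell by 0.60 ± 0.22 (adjusted p = 0.030). Of 2595 genes tested, 349 were higher and 383 lower in non-classical-like cells.

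**Figure D2:**
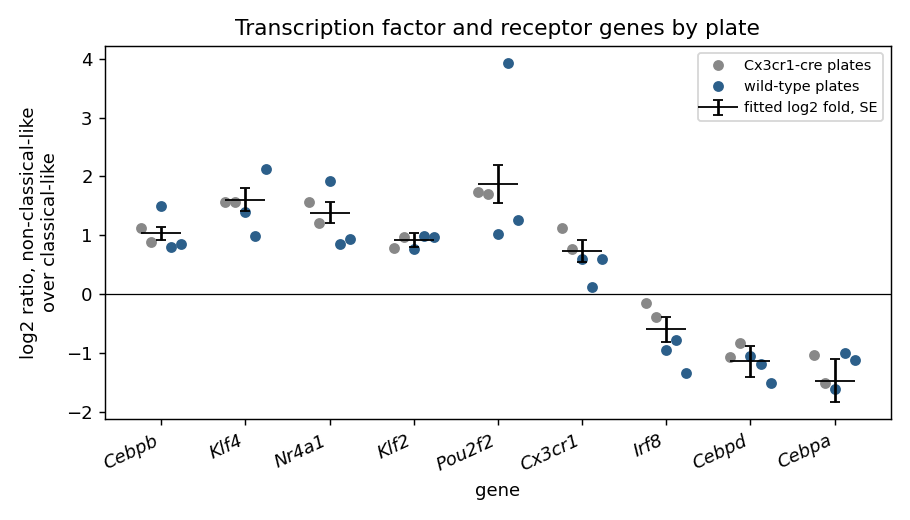
Log2 ratio of CPM (with 10 CPM added) in non-classical-like over classical-like cells for 9 genes on each of the 5 plates of total monocytes (points), with the fitted log2 fold and its SE (black). Cebpb lies above 0 on 5 of 5 plates, and Cebpa and Cebpd lie below 0.

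The largest rises in non-classical-like cells included the survival genes Bcl2a1b (log2 fold 3.22 ± 0.34), Bcl2a1a (3.0 ± 0.43) and Bcl2a1d (2.76 ± 0.30), near-identical copies whose reads the counting could have split between them. Lilra5, an activating receptor gene, rose by 2.91 ± 0.34, the integrin gene Itgax by 2.65 ± 0.33, the transglutaminase gene Tgm2 by 2.60 ± 0.32, Tcf7l2, which encodes a factor of the Wnt pathway, by 2.51 ± 0.48, and S1pr5, a sphingosine-1-phosphate receptor gene, by 2.36 ± 0.24. Mthfs, Smc6, Dusp16 and L1cam rose by 2.79, 2.74, 2.70 and 2.31. Among the largest falls, Mnda had a log2 fold of -2.49 ± 0.30, Ifi205 of -2.45 ± 0.51, Fgl2 of -2.17 ± 0.35, the lectin gene Clec4a2 of -2.15 ± 0.27, the complement gene C3 of -1.96 ± 0.17 and the immediate-early gene Fos of -1.91 ± 0.43. Slfn1, Gng2, Ms4a8a, Ethe1, Capg and Hopx had log2 folds between -2.10 and -1.90.

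Several of the fixed gene lists moved as groups. Of 20 antimicrobial and granule genes tested, 0 were higher and 13 lower in non-classical-like cells (14 lower adjusted over the list alone), with Lyz2, which encodes lysozyme, at -1.28 ± 0.07, S100a6 at -1.37 ± 0.09 and S100a4 at -1.09 ± 0.09. The camera test gave adjusted p = 5.5e-07 with the preset correlation and 0.015 with an estimated one. Of 49 ribosomal protein genes 0 were higher and 30 lower (33 lower adjusted over the list alone), for example Rplp0 at -0.79 ± 0.08. The adjusted p = 1.6e-07 became adjusted p = 0.021 with an estimated correlation. Of 36 genes of oxidative phosphorylation 0 were higher and 13 lower (13 adjusted over the list alone; adjusted p = 3e-04, and 0.015 with an estimated correlation). Of 18 interferon-stimulated genes 0 were higher and 9 lower (1 higher and 9 lower adjusted over the list alone), among them Ifi27l2a at -1.32 ± 0.13 and Ifitm3 at -0.51 ± 0.08. This list's adjusted p = 4.2e-06 became an adjusted p = 0.12 with an estimated correlation. The myeloid transcription factors (12 higher and 5 lower of 28; 13 and 5 adjusted over the list alone) and the list of chemokine receptors and adhesion (12 higher and 3 lower of 22; 13 and 3) were called with the preset correlation (adjusted p = 0.0091 and 0.0046). Both lost the call with an estimated correlation (adjusted p = 0.17 and 0.12). The lipid list, with Apoe at 0.98 ± 0.09 and Pltp at 1.74 ± 0.29, had 3 higher and 0 lower of 7 (3 and 0 adjusted over the list alone; adjusted p = 0.024, and 0.17 with an estimated correlation). Genes moved both ways in the Fc and complement receptor list, where Fcgr4, which encodes an activating Fc receptor, rose by 1.92 ± 0.14 and Cd93 had a log2 fold of -2.27 ± 0.36 (5 higher and 9 lower of 17; 6 and 10 adjusted over the list alone; adjusted p = 0.079). H2-K1 (0.91 ± 0.09), B2m (0.64 ± 0.07) and H2-D1 (0.64 ± 0.08) of MHC class I rose, and the other 9 tested members of that list did not pass (3 higher adjusted over the list alone; adjusted p = 0.34). That list's median was -0.03 and its mean 0.12. The other 8 lists were not called by camera. The fry test, which asks whether a list moves on balance and not whether it differs from other genes, called 3 of these 8, lysosome (adjusted p = 2.6e-04), immediate-early and stress genes (0.0039) and survival and apoptosis (0.0043), and also the Fc and complement receptor (0.0029) and MHC class I lists (0.0040).

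The test was edgeR's quasi-likelihood test on UMIs summed per plate and class, with the plate as a block and Benjamini-Hochberg adjustment. Marker genes used to cluster were not tested. The count of 732 was 273 on the 3 wild-type plates alone, 451 and 428 without Cx3cr1-cre plate 1 or 2, 391 without the block and 214 with equal numbers of cells per class. Without low-count filter 367 genes were higher and 230 lower, at a median of 0.13 over all genes.

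MHC-II-like cells were then set against both other classes. They carried less Cebpb than non-classical-like cells (785 against 1517 CPM, log2 fold -0.89 ± 0.12, adjusted p = 1.5e-07), and a difference from the 748 CPM of classical-like cells did not pass (0.14 ± 0.14, adjusted p = 0.72). Nr4a1 stood at 0.19 ± 0.25 against classical-like (adjusted p = 0.82) and -1.19 ± 0.21 against non-classical-like cells (adjusted p = 2.4e-05). Cebpa was higher than in non-classical-like cells, by 2.07 ± 0.38. Klf4 was higher than in classical-like cells, by 1.19 ± 0.23 (adjusted p = 5.4e-04), and at -0.41 ± 0.19 against non-classical-like cells (adjusted p = 0.15). Klf2, Csf1r and Pou2f2 lay below the non-classical-like level (-0.70 ± 0.13, -0.41 ± 0.12 and -1.32 ± 0.35), while Cx3cr1, Irf8 and Sfpi1 passed against neither class (log2 folds of 0.33, -0.42 and 0.14 against classical-like and of -0.39, 0.19 and -0.29 against non-classical-like cells). Klf2, Csf1r and Pou2f2 stood at 0.23, 0.00 and 0.55 against classical-like cells and did not pass either.

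Against classical-like cells 47 genes were higher and 63 lower of 2595. Besides AC139759.1, a gene with a clone name only (4.65 ± 0.28), the largest rises were Itgax (2.62 ± 0.39), Tcf7l2 (2.04 ± 0.61), Abcg3 (1.97 ± 0.43), the receptor kinase gene Axl (1.85 ± 0.53), Myo1c, Pltp, Adrbk2, Tmem176b (1.53 ± 0.18), Tmem176a, Hsp90aa1 and Slc16a3. The largest falls were S100a9 (-2.90 ± 0.69), F10, which encodes coagulation factor X (-1.99 ± 0.33), C3 (-1.98 ± 0.22), Gstm1 (-1.94 ± 0.39), Tnfaip2, Hopx, Tmem38b, Mtus1, Tnfrsf21, Pyhin1, Emb and Ptplad2. Of 20 antimicrobial and granule genes 0 were higher and 13 lower (14 lower adjusted over the list alone), with Lyz2 at -1.08 ± 0.07 and Cybb at -0.69 ± 0.11 (adjusted p = 8.8e-08, and 0.012 with an estimated correlation). Neutrophil markers were also lower on each plate. They made 151 and 137 CPM (without TMM scaling) against 1056 and 793 on the Cx3cr1-cre plates. On the wild-type plates they made 495, 114 and 454 against 1547, 400 and 500. The origin of granule transcripts is taken up below. Interferon-stimulated genes had 0 of 18 past the threshold in either direction (0 adjusted over the list alone), with a median log2 fold of -0.29 and an adjusted p = 0.0055 that became an adjusted p = 0.46 with an estimated correlation. The other 15 lists were not called by camera. The fry test called 4 of them, oxidative phosphorylation (adjusted p = 0.0035), MHC class I (0.0073), Fc and complement receptors (0.017) and lysosome (0.049).

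Against non-classical-like cells 202 genes were higher and 146 lower of 2595. AC139759.1 (4.28 ± 0.23), Tmem176a (2.98 ± 0.33), Tmem176b (2.85 ± 0.19), Axl (2.85 ± 0.51), Rnd3 (2.64 ± 0.57), Slc29a3, Cebpa, Olfm1, Sulf2, SNORD79, Dnajb14 and the Fc receptor gene Fcgr1 (1.61 ± 0.30) rose most. Cd82 (-2.61 ± 0.46), S1pr5 (-2.56 ± 0.30), Dusp16 (-2.37 ± 0.33), the Bcl2a1 genes (Bcl2a1b at -2.19 ± 0.36), Fam134b, Smc6, Spata13, Tgm2, Lilra5 and Samsn1 fell most. Of 49 ribosomal protein genes 26 were higher and 0 lower (37 higher adjusted over the list alone; adjusted p = 2.8e-12, and 0.014 with an estimated correlation). Interferon-stimulated genes (6 higher and 1 lower of 18; 7 and 1 adjusted over the list alone) and chemokine receptors and adhesion (1 higher and 9 lower of 22; 1 and 10) were called with adjusted p = 0.014 and 0.017, and with an estimated correlation had adjusted p = 0.32 and 0.21. The fry test did not call the interferon-stimulated genes (adjusted p = 0.059). It called 6 lists that camera did not: lysosome (0.012), oxidative phosphorylation (0.022), survival and apoptosis (0.035), myeloid transcription factors (0.036), and actin cytoskeleton and lipid metabolism (0.039 each). In the same edgeR fit, the count of 110 genes against classical-like cells was 42 on the 3 wild-type plates alone, 48 and 71 without Cx3cr1-cre plate 1 or 2 and 26 without the block. The count of 348 against non-classical-like cells was 150 on the wild-type plates alone (67 higher and 83 lower), 224 and 198 without Cx3cr1-cre plate 1 or 2 and 115 without the block. Without low-count filter the split of the 298 genes against non-classical-like cells was 57 higher and 241 lower, at a median of -0.38 over all genes.

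The Ly6C-int plate was compared with the wild-type plates to describe the cells in the intermediate gate. Over all kept cells, genes of MHC class II were higher: H2-Aa at 5065 against 1610 ± 181 CPM (SD, n = 3; log2 fold 1.65 ± 0.15), H2-Ab1 at 3892 against 1192 ± 182 (1.71 ± 0.18), H2-Eb1 at 2752 against 770 ± 93.3 (1.83 ± 0.19) and Cd74, the invariant chain, at 7220 against 3064 ± 225 (1.24 ± 0.13), each with adjusted p of 3.5e-06 or below. AC139759.1 (1.76 ± 0.32) and Tmem176b (1.52 ± 0.25) rose with them, as did Tagln2 (0.96), Tgfbi (0.88) and Crip1 (0.73). The chemokine gene Cxcl10 was at 414 CPM against 25.9 (3.98 ± 0.43, adjusted p = 5.8e-06), S100a9 at 991 against 109 (3.19 ± 0.45) and Ttc39c at 145 against 8 (4.23 ± 0.70). Ly6c2, the gene of the protein that the gate selects on, was lower (-1.24 ± 0.21, adjusted p = 0.0034), as were the receptor gene Cd300e (-2.34 ± 0.32), the non-coding RNA Malat1 (-1.55 ± 0.16), AC113316.1 (-1.57 ± 0.23), Adar (-3.42 ± 0.75), Skint3 (-2.80 ± 0.53) and Krt80 (-1.07 ± 0.24). In all, 16 of 6454 genes were higher and 7 lower. S100a9 is a neutrophil marker, and the neutrophil list was at 2827 CPM on this plate. All genes were tested here, markers included. The class shares alone give log2 folds of 1.39 for H2-Aa, 1.38 for H2-Ab1, 1.41 for H2-Eb1 and 1.23 for Cd74, and of -0.47 for S100a9, -0.27 for Cxcl10 and -0.17 for Malat1.

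**Figure D3:**
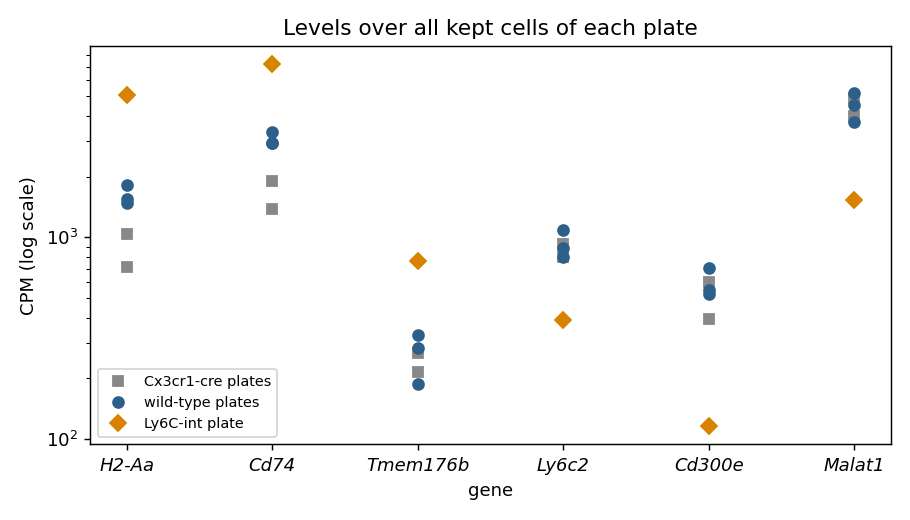
CPM over all kept cells of each plate for 6 genes, on a log axis; each point is 1 of the 6 plates. H2-Aa, Cd74 and Tmem176b lie highest, and Ly6c2, Cd300e and Malat1 lowest, on the Ly6C-int plate.

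Within non-classical-like cells, 25 of 5247 genes were higher on the Ly6C-int plate and 8 lower. The rises included Cxcl10 (4.82 ± 0.53), S100a9 (2.84 ± 0.40), Tmem176b, S100a13, Uqcrc2, Tgfbi (1.16 ± 0.26), Nme2, Tmsb10 (1.05 ± 0.18), Plac8 (0.85 ± 0.12), Ifitm3 (0.72 ± 0.11), S100a4 (0.72 ± 0.14) and Crip1 (0.70 ± 0.16), and from the lists Clec4n (3.30 ± 0.74), Vim (0.67 ± 0.17) and Rps28 (0.66 ± 0.16). Malat1 (-1.75 ± 0.13), AC113316.1 (-1.32 ± 0.16), Btg1 (-1.38 ± 0.34), Sf1, Skint3, Fam117b, Krt80 and Actb (-0.28 ± 0.07) were lower. Within classical-like cells the plate gave 21 cells, and 1 of 1664 genes was higher and 4 lower, with Lyz2 at -0.75 ± 0.13, Malat1 at -1.77 ± 0.34 and AC113316.1 at -2.11 ± 0.23. The median log2 fold of all tested genes was -0.18 there, so these values lie that much nearer to 0 relative to it. Ribosomal protein genes were the list called by camera in the pooled cells and in non-classical-like cells (0 and 1 of 51 and 50 members higher, 5 and 9 adjusted over the list alone; adjusted p = 3.5e-04 and 0.0012). With an estimated correlation these had adjusted p = 0.61 and 0.64, and by fry 0.19 and 0.17. In classical-like cells camera called no list, and fry called glycolysis (adjusted p = 0.028), interferon-stimulated genes and lysosome (0.029 each), Fc and complement receptors (0.038) and oxidative phosphorylation (0.047). The lone plate was assumed to vary like the others in the edgeR fit, and the count of 23 genes ranged from 15 without wild-type plate 3 to 53 without Cx3cr1-cre plate 1, with 52 without Cx3cr1-cre plate 2, 35 without wild-type plate 1 and 59 when both Cx3cr1-cre plates were left out. The count of 33 in non-classical-like cells was 20 without wild-type plate 2 and 53 without wild-type plate 1, and that of 5 in classical-like cells was 3 without either Cx3cr1-cre plate.

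The Cx3cr1-cre plates were compared with the wild-type plates as sets of plates that differ in genotype, age, sequencing batch and depth per cell at once. Of 6454 genes 135 were higher and 377 lower. The Y-linked genes Eif2s3y and Ddx3y summed to 128 and 96 UMIs on the Cx3cr1-cre plates and to 0 on the wild-type plates, although all 6 plates are labelled female. The haemoglobin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 were higher (log2 folds of 8.76, 7.35, 7.05 and 6.80). The Hba genes are closely similar copies of each other, as are the Hbb genes. Over all wells these genes made 3945 UMIs on Cx3cr1-cre plate 1, where 4 wells held at least 50 each. They made 79 on Cx3cr1-cre plate 2 and 5, 1 and 5 on the wild-type plates. Saa3, which encodes an acute-phase protein (4.54 ± 0.48), Lrg1 (5.35 ± 0.81), the metallothionein gene Mt1 (4.07 ± 0.67), Hebp1, Card9 and Lbp were also among the largest rises. The granule genes Ngp (0 UMIs on the Cx3cr1-cre and 169 on the wild-type plates), Camp (-6.08 ± 0.80) and Ltf (-5.77 ± 1.22), with Arg1 (0 against 49 UMIs), Cxcl9 (0 against 30), Ffar2, Hspa1a, Ly6i, AC132082.1, Cd83 (-2.83 ± 0.46), Rpl17-ps3 and D14Ertd668e, were the largest falls. Neutrophil markers as a list differed between the wild-type plates as given above. Granule transcripts of the wild-type plates may have been exchanged between wells, as set out below. The falls of Ngp, Camp and Ltf thus need not lie in the cells.

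Abundant genes of antigen presentation by MHC class I were lower on the Cx3cr1-cre plates: B2m at 6725 ± 173 (SD, n = 2) against 11039 ± 255 CPM (n = 3; -0.72 ± 0.06, adjusted p = 2.5e-07), H2-K1 (-0.89 ± 0.11) and H2-D1 (-0.45 ± 0.08). The MHC class I list had 0 higher and 7 lower of 17 (7 lower adjusted over the list alone; adjusted p = 0.001, and 0.23 with an estimated correlation). Interferon-stimulated genes had 0 higher and 12 lower of 30 (14 lower adjusted over the list alone), with Ifi27l2a at -1.12 ± 0.16 and Ifitm3 at -0.57 ± 0.09 (adjusted p = 1.3e-06, and 0.16 with an estimated correlation). Ribosomal protein genes had 0 higher and 21 lower of 51 (32 lower adjusted over the list alone), with Rpl34 at -1.47 ± 0.12 (adjusted p = 8.4e-10, and 0.38 with an estimated correlation). Immediate-early and stress genes had 0 higher and 3 lower of 23 (3 lower adjusted over the list alone), with Dusp1 at -2.16 ± 0.27 (adjusted p = 0.003, and 0.58 with an estimated correlation). The fry test called the first 3 of these lists (adjusted p = 0.023, 0.017 and 0.023) and not the last (0.22), and it called actin cytoskeleton and migration (0.017), which camera did not (0.28). Apoe (-0.94 ± 0.10), Actb (-0.67 ± 0.07), Tmsb4x (-0.65 ± 0.06), Klf2 (-0.65 ± 0.13), Cx3cr1 (-1.06 ± 0.19) and Cebpb (-0.41 ± 0.12, adjusted p = 0.045) were lower, and Chi3l3 (1.31 ± 0.15), Klf13 (0.77 ± 0.16), Id3 (2.48 ± 0.53), Cd93 (1.51 ± 0.29) and Cebpd (1.07 ± 0.29) higher. Actb and Tmsb4x, abundant genes outside the MHC class I list, thus fell by about as much as B2m. Depth per cell also differed between these plates, and its part in the falls was not tested. The classical-like share was also larger on these plates, as given above, and Cebpb did not pass within classical-like (-0.05 ± 0.21, adjusted p = 0.95) or non-classical-like cells (-0.26 ± 0.12, adjusted p = 0.21).

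Part of these differences was also present within a class. Among non-classical-like cells 84 of 5247 genes were higher and 320 lower, with B2m at -0.59 ± 0.05, Apoe at -0.78 ± 0.09, Rpl34 at -1.53 ± 0.13, Klf2 at -0.57 ± 0.14 and Cx3cr1 at -0.73 ± 0.21. Among classical-like cells 42 of 1664 were higher and 121 lower, with Saa3 at 5.66 ± 0.74, Irf7 at -1.64 ± 0.30, Ccl6 at -1.03 ± 0.16, Rpl34 at -1.41 ± 0.18 and Apoe at -0.80 ± 0.16. Interferon-stimulated genes had 0 higher and 9 lower of 21 in classical-like cells (13 lower adjusted over the list alone) and 0 higher and 3 lower of 26 in non-classical-like cells (9 lower). Their adjusted p = 1e-06 and 3.1e-05 became adjusted p = 0.26 and 0.27 with an estimated correlation. Ribosomal protein genes had 4 lower of 46 in classical-like cells (4 adjusted over the list alone) and 30 lower of 50 in non-classical-like cells (40). These had adjusted p = 0.0039 and 9.5e-13, and adjusted p = 0.31 and 0.27 with an estimated correlation. The MHC class I list had 0 higher and 7 lower of 17 in non-classical-like cells (7 adjusted over the list alone; adjusted p = 0.0055, and 0.27 with an estimated correlation). In classical-like cells it had 0 higher and 2 lower of 12 (2 lower adjusted over the list alone) and was not called (adjusted p = 0.30, and 0.48 with an estimated correlation). By fry the interferon-stimulated and ribosomal lists were called in classical-like cells (adjusted p = 0.041 each). In non-classical-like cells fry called the ribosomal list (0.027) but not the interferon-stimulated (0.10) or MHC class I list (0.058). The count of 512 over all cells was 295 without Cx3cr1-cre plate 1. That of 163 in classical-like cells was 33, 59 and 106 without Cx3cr1-cre plate 1, Cx3cr1-cre plate 2 or wild-type plate 2. That of 404 in non-classical-like cells was 177 and 233 without Cx3cr1-cre plate 1 or 2. With DESeq2's test 46 genes were higher and 297 lower over all cells.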

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

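Tests on Y-linked transcripts and on granule transcripts were chosen after the result was seen, except the test of Cxcl10. The fold of non-classical-like over classical-like cells differed between the Cx3cr1-cre and the wild-type plates for 6 genes by an interaction term in edgeR (3 higher, 3 lower of 5012). The differences of log2 folds were -3.65 ± 0.40 for S100a8, -3.87 ± 0.76 for Lcn2, -3.32 ± 0.72 for S100a9, 0.93 ± 0.15 for Ccl6, 1.12 ± 0.23 for Gm11428 and 0.56 ± 0.13 for Plac8. S100a8, Lcn2 and S100a9 are among the granule transcripts taken up below. In non-classical-like cells those made 2123, 524 and 581 CPM (without TMM scaling) on wild-type plates 1 to 3 and 98 on each Cx3cr1-cre plate. These 3 differences may thus reflect granule molecules spread over wild-type wells and need not lie in the cells. Between the Ly6C-int and the wild-type plates the fold differed for 19 genes (18 higher and 1 lower of 3359), with 0.81 ± 0.12 for Lyz2, 1.54 ± 0.27 for Tmsb10, 1.21 ± 0.23 for Ifitm3 and 1.02 ± 0.20 for Plac8; the Ly6C-int plate is a single plate with 21 classical-like cells. The 24 empty wells held 1046 UMIs in all.

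Granule transcripts (S100a8, S100a9, Camp, Ngp, Ltf and Lcn2) made 502, 97, 166 and 711 UMIs on wild-type plates 1 to 3 and the Ly6C-int plate, and 321 and 232 on the Cx3cr1-cre plates, where classical-like cells held most of them (881 and 635 CPM without TMM scaling). A sort of CD115+ cells without lineage markers such as Ly6G is meant to keep neutrophils out. Neutrophils sorted into wells would put most of these UMIs in few wells. Wells with at least 20 held 34.9% of them on the Ly6C-int plate and 41.1% and 29.3% on the Cx3cr1-cre plates. They held 0% on wild-type plates 1 to 3, where the fullest kept well had 16, 4 and 5. That cut was not scaled to depth per cell, so the 0% does not decide on this source. The UMIs lay in 167, 71 and 95 kept wells of these plates, so they were not confined to few kept wells. Wells under the minimum of UMIs per cell are not in these counts. Sorted neutrophils thus stay open as a source of part of these UMIs on every plate. The variance of granule UMIs was 3.98, 1.66 and 2.39 times the Poisson value on wild-type plates 1 to 3 and 15.7 times on the Ly6C-int plate. That Poisson value was in proportion to the total UMIs of each well. Free RNA in equal amounts per well was not modelled, so these values do not decide on it. Exchange of molecules between wells of the same position is a candidate source: after accounting for total UMIs, counts at the same position correlated in the 6 pairs of plates of that sequencing batch (partial rank correlation of at least 0.502 in the 3 pairs without wild-type plate 2, and 0.462, 0.357 and 0.359 with it, each at permutation p = 1e-05, the smallest the permutations can give), but not detectably in the Cx3cr1-cre pair, which also shares a batch (0.0689, permutation p = 0.234), while the 8 pairs across batches ranged from -0.188 (Cx3cr1-cre plate 2 with wild-type plate 1, permutation p = 0.00225, adjusted p = 0.00482) to 0.0603, so the measure can pass, with a negative sign, between plates of different batches. The S100a9 rise on the Ly6C-int plate may share this source (0.472 against granule counts of wild-type plate 1). That plate held 239 S100a9 UMIs, more than the 63, 17 and 7 of wild-type plates 1 to 3. The mix of granule genes differed too, with Ngp at 72 UMIs against 109, 55 and 5. Which plate gave such molecules, and other causes of a pattern shared by position, were not tested. The Cxcl10 rise showed no relation to those granule counts (-0.0150, permutation p = 0.807). Exchanged Cxcl10 molecules would follow wells rich in Cxcl10, which were not examined, so exchange of Cxcl10 is not excluded. No biological explanation was tested.

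The Cx3cr1-cre plates, labelled female, held 253 UMIs of the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty in 187 of 671 cells (169.5 CPM). The other plates held 0, which allows up to 2.75 CPM. Xist, transcribed from the inactive X chromosome, had 0 UMIs on the Cx3cr1-cre plates, where the rate of the other plates would give 30.1, and 22 UMIs on the other plates. Leakage of male RNA into wells with female cells would leave Xist near that rate, and its upper 95% Poisson bound is 12.3% of it, which argues against leakage. Together with the Y-linked UMIs, this argues against the female label of these plates. Male animals would give such values: cells with a Y-linked UMI were 92.4% of the number that a Poisson draw from every cell gives. Sex would then differ along with genotype, age, sequencing batch and depth per cell in the Cx3cr1-cre comparison, and these cannot be told apart.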

How the results depend on the processing

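The mixture model for classes and the removal of wells rich in haemoglobin were chosen after the result was seen; the other settings for the values below were planned. For each count named below the cause of the change was not tested, beyond the smaller number of genes tested (724 with equal numbers of cells, 1138 on the wild-type plates alone). With equal numbers of cells, without replicate block and on the 3 wild-type plates alone, the count was 214, 391 and 273 for non-classical-like against classical-like cells (732), 59, 26 and 42 for MHC-II-like against classical-like cells (110), and 144, 115 and 150 for MHC-II-like against non-classical-like cells (348). For the Ly6C-int plate over all cells (23) it was 15 with the DESeq2 Wald test, 48 without low-count filter and 59 with only the 2 groups in the fit, and in classical-like cells (5) it was 8 with classes from 1000 variable genes and 3 with the mixture model. With each plate left out in turn the counts ranged from 428 to 754, from 48 to 107 and from 198 to 310 for the class comparisons in that order. They ranged from 15 to 53 for the Ly6C-int plate, 3 to 7 within classical-like and 20 to 53 within non-classical-like cells, and from 295 to 534, 33 to 164 and 177 to 411 for the Cx3cr1-cre plates. Where 1 Cx3cr1-cre plate was left, it was assumed to vary like the other groups, as was the Ly6C-int plate. No plate could be left out on the Ly6C-int side.

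Differences of shares from the wild-type plates moved with the settings. For the Ly6C-int plate the classical-like difference of -10.6 points was -5.58 with at least 200 UMIs, -17.3 with at least 800, -3.60 with 1000 variable genes and -2.39 in cells thinned to 400 UMIs. The non-classical-like difference of -15.6 was -20.9 with at least 800, -17.6 with variable genes, -11.3 with the mixture model and -19.5 in thinned cells. The MHC-II-like difference of 26.1 was 21.6 with at least 200, 38.2 with at least 800, 21.2 with variable genes or the mixture model, 25.5 at Leiden resolution 1.0 and 21.9 in thinned cells. For the Cx3cr1-cre plates the classical-like difference of 14.3 was 16.4 with at least 200, 8.74 with at least 800, 10.7 with variable genes and 16.8 in thinned cells. The non-classical-like difference of -12.4 was -14.9 with at least 200, -8.95 with variable genes and -15.0 in thinned cells, and reversed to 2.05 with at least 800 and to 5.18 at Leiden resolution 1.0, where a cluster without a name took at least 20.3% of the kept cells of each wild-type plate and at most 4.40% of each Cx3cr1-cre plate. The MHC-II-like difference of -1.87 was -10.8 with at least 800 and -3.77 with the mixture model.

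With an estimated correlation, 3 of 7, 1 of 2 and 1 of 3 lists were called in the class comparisons in the same order. In the Ly6C-int comparison the number called was 0 of 1 over all cells and 0 of 1 in non-classical-like cells, and in the Cx3cr1-cre comparison 0 of 4, 0 of 2 and 0 of 3 over all, classical-like and non-classical-like cells. Values of named genes were counted as unchanged where direction and side of the threshold were kept. They were also counted so where the gene passed in neither fit, whatever its direction. Settings that did not test a gene gave no value for it. Unchanged were 1283 of 1337 values for non-classical-like against classical-like cells. For MHC-II-like cells these were 711 of 851 against classical-like and 1090 of 1176 against non-classical-like cells. Over all cells these were 242 of 266 for the Ly6C-int plate and 953 of 1021 for the Cx3cr1-cre plates. Within classical-like and non-classical-like cells these were 25 of 27 and 183 of 207 for the Ly6C-int plate, and 343 of 444 and 527 of 604 for the Cx3cr1-cre plates; in classical-like cells of the latter 34 of 46 genes lost the threshold in at least 1 setting. The oxidative phosphorylation gene Atp5h reversed with equal numbers of cells, to 0.030 in non-classical-like against classical-like cells and to -0.17 in MHC-II-like against non-classical-like cells. Of 100 splits of the 10 sums of 2 classes into groups of 5, 1, the real one, gave a count as large in each class comparison. The highest other count was 162 against 732, 14 against 110 and 19 against 348. Of these splits 16 part the 2 classes of every plate, with a highest other count of 0, 3 and 2, and 16 are too few for a share under 0.05. The classes were clustered from the same cells, so this comparison does not measure chance.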

Other observations

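The tests of a shift towards classical-like cells and of RNA per cell were chosen after the result was seen; those on MHC-II-like genes were planned. Genes that were higher in classical-like than in non-classical-like cells on the Cx3cr1-cre plates alone, clustering markers left out, were followed into the non-classical-like cells of the Ly6C-int plate. Of 150 such genes tested, 97 lay higher there than in wild-type non-classical-like cells, with a median log2 fold of 0.45 against -0.07 for other genes (camera p = 4.98e-06, and p = 0.0318 with an estimated correlation). Of 253 genes higher in non-classical-like cells, 69 lay higher and the median was -0.41 (p = 0.0216 with an estimated correlation). A partly classical-like transcript programme in non-classical-like cells of the intermediate gate is one hypothesis; with classes from 1000 variable genes the first p with an estimated correlation was 0.0529, and with a mixture model 0.0252. Within the 21 classical-like cells of that plate the sets leaned the other way. Whether they passed with an estimated correlation depended on how classes were made. Of 91 genes higher in classical-like cells 26 lay higher (median -0.47 against -0.15 for other genes). The genes higher in non-classical-like cells had a median of 0.17 against -0.19 for other genes. With classes from 1000 variable genes the medians of the 2 sets were -0.45 against -0.07 and 0.49 against -0.09. In classical-like cells of that plate classical markers made 10026 CPM (without TMM scaling), and 16040 to 18126 on the wild-type plates. Non-classical markers made 5512 there and 3098 to 3715 on the wild-type plates. In non-classical-like cells classical markers made 4371, and 3125 to 3294 on the wild-type plates. These markers also set the classes. Whether the classes of that plate lie nearer to each other thus stays open on the classical-like side, and cells assigned to the wrong class were not tested as a source. The result rests on 1 plate.

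MHC-II-like cells gave 44.4% of the UMIs of the Ly6C-int plate and 14.9% of those of the wild-type plates. Over 54 genes higher in MHC-II-like than in non-classical-like cells, markers left out, the median log2 fold of the Ly6C-int plate was 0.38, which is 1.65 times the 0.23 that class shares give. The share values came from rates without TMM scaling, with 1e-05 per UMI added, so the ratio compares unlike measures. Within non-classical-like cells the same genes had a median of 0.67, which is 1.76 times the pooled median. These genes were chosen as low in cells that include the same wild-type non-classical-like cells. That choice favours a rise here, so these values do not decide whether levels rose within the class. MHC-II or dendritic cell-like markers made 4181 CPM (without TMM scaling) in non-classical-like cells of the Ly6C-int plate and 1702 to 2024 on the wild-type plates. Cells assigned to the wrong class were not tested as a source. The parts of shares and levels cannot be told apart with 1 plate in the gate. For Cd74 the shares give 1.23 and 1.24 was observed, and for H2-Aa they give 1.39 and 1.65 was observed. For H2-Ab1 and H2-Eb1 they give 1.38 and 1.41, and the observed folds, given above, lay further over the share values.

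UMIs per spike-in UMI were higher in MHC-II-like than in non-classical-like cells on 6 of 6 plates, by 1.81 ± 0.282 times (SD, n = 6; exact two-sided p = 0.0312, the smallest possible), and in classical-like cells by 1.40 ± 0.253 times. Class assignment depends on depth, so these ratios decide nothing alone. With classes from cells thinned to 400 UMIs, a setting planned for the shares and applied to this ratio after the first ratios were seen, the ratios were 1.73 ± 0.252 and 1.23 ± 0.205, again above 1 on 6 of 6 plates (exact p = 0.0312 each). A larger RNA content of MHC-II-like cells is a hypothesis that these values leave open, and the minimum of UMIs per cell could then change class shares.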
